A study of Mus musculus with 6 samples.

How the data were processed

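RNA was measured in mouse retina by sequencing. Per the labels' protocols, retinas of C57BL/6 mice aged 10 weeks were homogenised, an anti-HA antibody and Protein G magnetic beads were used to pull down tagged material, and RNA was isolated from the beads. HA is a short peptide tag; which protein carried it is not stated in the labels, which give the genotype as wild type and the cell type as retinal ganglion cells. The 6 libraries fall into 2 groups of 3, naive and SOHU, and each library was placed in its group by its labelled condition. SOHU is a model of raised eye pressure in which silicone oil is put into the anterior chamber of the eye, here 1 week before the retinas were taken. The labels do not say whether the libraries of a group came from separate animals or pools.

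The authors deposited raw read counts per gene for each library, together with 1 table of the same counts for all libraries. All 6 columns of that table were equal to the files of the single libraries, so using it in their place could change nothing. Per the submitters' processing notes, bcl2fastq 2.17, Trim Galore, HISAT2, HISAT, MultiQC and featureCounts were used, with genome build mm10; their order, settings and the other versions are not given in the sources used here, nor is the annotation release, the strand setting of the counting or the treatment of reads that align to several places. The files list 55335 genes with the coordinates of their exons, of which 55154 were given a symbol by Ensembl identifier from GENCODE release M21, 54587 of them with the same identifier version. No row lacked a gene and no column lacked a sample. Coordinates are those of the files, on mm10.

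Total counts were 26824919, 23151542 and 22303220 for naive replicates 1 to 3 and 25544710, 21691354 and 23702352 for SOHU replicates 1 to 3. Replicates of a group were compared before averaging: the chi-square per degree of freedom between the pairs within a group was 13.7 to 88.3, so no library was a second copy of another of its group.

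Genes with low counts were removed with filterByExpr by group, which left 17687 genes holding at least 99.84% of the reads of each library. Counts were scaled by TMM, with factors between 0.943 and 1.039, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, group as the only term). Changes are SOHU minus naive on the log2 scale with their standard errors, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Normalised levels are CPM (counts scaled to a common library size) after TMM, given as mean ± SD over 3 libraries. The common biological coefficient of variation was 22.3%. Log2 CPM for list levels and principal components used a prior count of 2.

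Before the data were examined, 34 gene lists were fixed, 20 of pathways and 14 of cell types, and all other choices below were fixed at the same time unless a sentence says otherwise. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01 between genes, adjusted within each kind of list, and again with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. For each list, members past the threshold were counted over all genes tested and "adjusted over the list alone". A total of 2 list symbols were not found (Hbb-b1 and Hbb-b2). Lists overlap: 5 of the ganglion cell markers (Nefl, Nefm, Nefh, Stmn2, Tubb3) are also in the axonal transport list.

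Genes named in the text follow a fixed rule: Nmnat2, the gene of the series title; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean log2 CPM of at least 3, no overlap between the groups and a symbol other than a predicted or clone name; up to 4 members of each list with the smallest p; and the 5 most abundant genes. Of the 134 genes named for their change, 104 follow this rule, and 30 were named after their values were seen, because a list had 5 or fewer genes on one side or as an example.

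Since strand use is not stated, reads of overlapping genes cannot be assigned with certainty. A total of 16 of the named genes share exon bases with another gene that reached at least 10% of their level, in 13 cases on the opposite strand, and their values are uncertain in that respect: Nefm and Nefl (with each other), Stk32c, Far2, Naprt, Mapk8ip3, Cebpb, Dusp1, mt-Atp6, mt-Co3, Fdft1, Cyp51, Kcnip4, Bfsp2, Cnp and Atp6v1h. Nmnat2 shares exon bases with no other gene of the files. Mitochondrial transcripts, crystallins and ribosomal proteins have close copies elsewhere in the genome and are uncertain as well.

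The fit was tested on simulated data with the real genes, library sizes and spread of the SOHU and naive comparison, 200 genes being changed. Among 17009 genes in that fit it called 8% of genes changed 1.5-fold, 46.9% of those changed 2-fold, 79.6% of those changed 3-fold and 93.8% of those changed 4-fold, and 8 of its 119 calls (6.7%) were unchanged genes. In a second simulation of 17716 genes, a list of 20 genes raised 1.5-fold had a camera p of 4.2e-26, and 1 of 20 unchanged lists had a p under 0.05; the simulated genes varied independently of each other, unlike real ones.

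Alternatives were the size factors of DESeq2, upper-quartile factors, other low-count filters, the Wald test of DESeq2 1.42.0, limma-voom, the robust option off, the replicate number as a block, a gene length trend removed, rod marker level as a covariate, background lists left out, and each library left out in turn. A scaling to the ganglion cell markers and the omission of pairs of libraries were chosen after seeing the data. Exact permutation tests were two-sided; with 3 libraries against 3 their smallest possible p is 0.1. Symbol stems were tested with Fisher's exact test in SciPy 1.17.1, and plots were made with matplotlib 3.10.9.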

Results

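RNA pulled down with an anti-HA antibody from mouse retina was sequenced to profile retinal ganglion cells, the neurons whose axons form the optic nerve, in naive mice and in mice with silicone oil-induced ocular hypertension (SOHU), a model of glaucoma. There were 3 naive and 3 SOHU libraries, the latter from retinas taken 1 week after the oil was injected, with 21691354 to 26824919 counted reads each. The first principal component held 51.9% of the variance and placed the naive libraries at -63.3, -23.6 and -35.1 and the SOHU libraries at 62.5, 49.5 and 9.9. Because the labels do not say that the libraries of a group came from separate animals, p-values measure only the spread between these samples, which may be technical.

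The series title names Nmnat2, which encodes an axonal enzyme of NAD synthesis, so its level was compared first. Nmnat2 (ENSMUSG00000042751.14, mm10 chromosome 1, 152954993 to 153119261, plus strand) fell from 45.3 ± 8.09 CPM in naive to 25.6 ± 5.32 CPM in SOHU (SD, n = 3 each), a 1.77-fold decrease. It had 1419, 937 and 928 reads in the naive libraries and 526, 517 and 779 in the SOHU libraries, so that all SOHU libraries lay below all naive libraries. The log2 fold change was -0.82 (SE 0.19, 95% interval -1.26 to -0.40, edgeR adjusted p = 0.0248), and the exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. In the same libraries the retinal ganglion cell markers had a median log2 fold change of -1.06, and 20 of those 22 markers fell further than Nmnat2. Scaled to these markers, a comparison chosen after seeing the data, Nmnat2 had a log2 fold change of 0.22 (SE 0.33, adjusted p = 0.546). Nmnat2 also missed the threshold without naive replicate 1 (adjusted p = 0.116), naive replicate 2 (0.0564), naive replicate 3 (0.0759) or SOHU replicate 2 (0.0885).

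**Figure D1:**
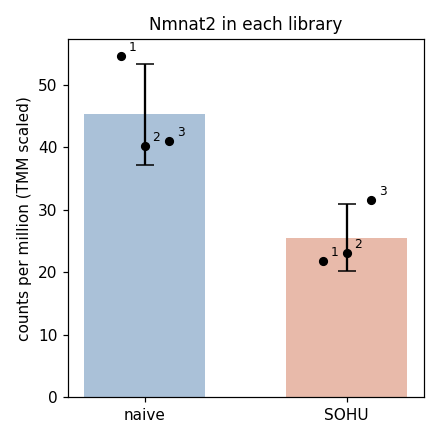
Nmnat2 in CPM (TMM scaled, y axis) in the naive and SOHU groups (x axis). Bars are means of 3 libraries, error bars are SDs and points are libraries with their replicate number; the naive libraries sit between 40.3 and 54.6 and the SOHU libraries between 21.9 and 31.7.

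Across all genes, 2467 of 17687 tested (13.9%) differed between SOHU and naive, 1418 higher and 1049 lower. Of these, 763 were higher and 282 lower by more than 2-fold. With the libraries scaled to the ganglion cell markers instead, a setting chosen after seeing the data that took the median log2 fold change of all genes from 0.014 to 1.06, 12061 genes were higher and 2 lower. The rises named next are the largest under the naming rule, which leaves out genes with a mean log2 CPM under 3. Apoc1, an apolipoprotein, rose 6.93-fold (log2 fold change 2.79, SE 0.40, adjusted p = 0.00993). Lyz2, the lysozyme of macrophages, rose 6.64-fold (2.73, SE 0.49, adjusted p = 0.015). Crym, which encodes a thyroid hormone-binding crystallin, went from 600.3 ± 188.1 to 3788 ± 1963 CPM (SD, n = 3 each), and the cholesterol exporter Abca1 from 11.2 ± 3.43 to 70.2 ± 29.2 CPM. The metallothionein Mt2, Mfap2, Gpd1, the cytokine signalling inhibitor Socs3, the transferrin gene Trf, the astrocyte filament gene Gfap, Cela1 and the translation repressor gene Eif4ebp1 rose by 4.08- to 5.57-fold. The largest falls under the same rule were smaller. Nos1, the neuronal nitric oxide synthase, fell 2.84-fold (-1.51, SE 0.30, adjusted p = 0.0163), and Fam163a fell 2.83-fold. The prohormone convertase gene Pcsk1, the neurofilament genes Nefm and Nefh, the sodium channel subunit gene Scn4b, the nicotinic receptor gene Chrna3, Stk32c, Coro6, Far2, the neuronal elongation factor gene Eef1a2 and the ganglion cell transcription factor gene Isl2 fell 2.52- to 2.79-fold. Among the 5 most abundant genes, Apoe and Clu, both secreted lipid-binding proteins made by glia, rose 2.69- and 2.77-fold and the glycolytic gene Aldoa fell 1.74-fold. Ckb (-0.27, adjusted p = 0.362) and Eno1 (0.60, adjusted p = 0.186) did not pass. Groups did not overlap in 6905 genes (39.0%), where chance gives 10% on average over the possible splits. Genes do not vary independently, so a single split can lie far from that average, and the share in the other splits was not tested. The number of genes past the threshold depended on single libraries: in edgeR it was 0 without naive replicate 1 or without naive replicate 3. There, 3919 and 4251 genes had an unadjusted p under 0.05 in edgeR. In the same omissions limma-voom called 0 and 0 genes and DESeq2 1765 and 2182. The edgeR number was 887 without naive replicate 2, 2017 without SOHU replicate 1, 336 without SOHU replicate 2 and 3896 without SOHU replicate 3. The calls on single genes below therefore hold for the 6 libraries together.

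**Figure D2:**
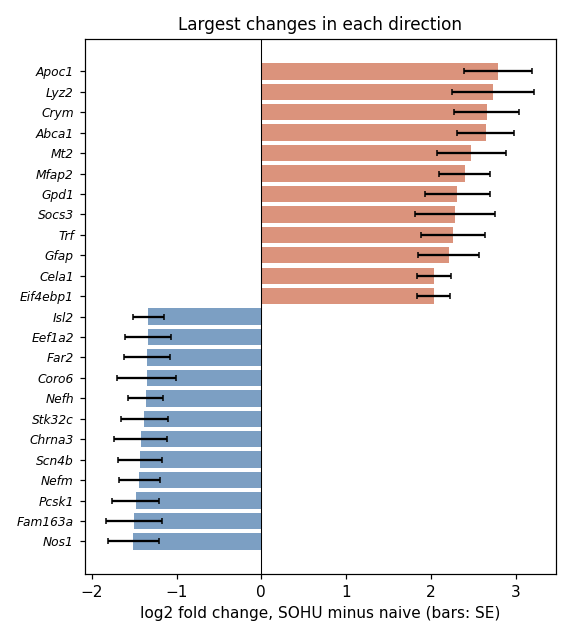
Log2 fold change (x axis, SOHU minus naive) of the 12 genes with the largest rise and the 12 with the largest fall under the naming rule (y axis); error bars are SEs of the edgeR fit, 3 libraries per group. Rises reach 2.79 in Apoc1 and falls -1.51 in Nos1.

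Markers of retinal ganglion cells fell together. Of 22 tested, 20 fell (21 adjusted over the list alone), among them Isl2 (-1.33, SE 0.18), Nefh (-1.36, SE 0.21), Nefm (-1.44, SE 0.24) and Nefl (-1.23, SE 0.21). Pou4f2 (-0.76) and Atoh7 (0.38), the latter a gene of ganglion cell development, did not pass. The list's camera adjusted p was 2.46e-13, and the adjusted p = 0.409 with an estimated correlation. Markers of ganglion cell types had a median of -0.69, with 8 of 24 lower (13 adjusted over the list alone), including the neuropeptide genes Cartpt (430.1 ± 91.1 to 214.6 ± 56.0 CPM, SD, n = 3 each) and Adcyap1 (log2 fold change -1.12), and Fstl4 (-1.31) (camera adjusted p = 5.38e-06; adjusted p = 0.409 with an estimated correlation). Amacrine and horizontal cell markers, of inner retinal interneurons, had a median of -0.73, and 5 of 18 fell (13 adjusted over the list alone, with 1 higher), namely Calb1, C1ql2, Gad2, Tfap2b and Meis2 (camera adjusted p = 8.51e-07; adjusted p = 0.409 with an estimated correlation). Bipolar cell markers had a median of -0.51 with 1 of 15 past the threshold, in all genes and adjusted over the list alone. That list's camera adjusted p was 0.0141, with adjusted p = 0.656 with an estimated correlation and 0.081 and 0.143 without naive replicate 2 and SOHU replicate 1. Photoreceptor markers passed in no case: 0 of 18 rod genes (median 0.08, camera adjusted p = 0.494) and 0 of 11 cone genes (median 0.06, camera adjusted p = 0.792), also adjusted over the list alone. Scaled to the ganglion cell markers, the medians of the ganglion cell type, amacrine and horizontal, bipolar, rod and cone lists were 0.34, 0.27, 0.42, 1.16 and 1.14, beside 1.06 for all genes. Camera sets a list against the other genes, so a shift common to all genes largely cancels in it. Its calls in that scaling are therefore no check on cell shares, and even the ganglion cell markers stayed lower there (adjusted p = 9.47e-18).

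Glial markers rose, and so did a part of the leukocyte markers. Of 17 Müller glia and astrocyte markers, 11 rose (15 adjusted over the list alone) with a median log2 fold change of 1.05, among them the potassium channel gene Kcnj10 (2.46-fold), Sox9 (2.20-fold), Aldh1l1 (2.60-fold) and Apoe (camera adjusted p = 2.42e-09; adjusted p = 0.409 with an estimated correlation). This list made up 1.71, 2.13 and 1.89% of the counts in the naive libraries and 5.59, 3.60 and 2.91% in the SOHU libraries. The ganglion cell marker list made up 0.785, 0.471 and 0.549% in the naive and 0.244, 0.221 and 0.321% in the SOHU libraries. For the rod list the shares were 0.803, 0.742 and 0.901% and 1.09, 0.703 and 0.753%. RNA of other cells was thus present in both groups, so a changed gene cannot be assigned to ganglion cells from these counts. Of 19 genes of reactive glia, 13 rose (15 adjusted over the list alone), including Gfap (4.63-fold), S100a6 (3.94-fold), the adhesion receptor gene Cd44 (3.99-fold) and the endothelin gene Edn2 (5.36-fold; 2.45 ± 1.68 to 13.1 ± 3.12 CPM, SD, n = 3 each). The list's median was 1.83 (camera adjusted p = 3.01e-12; adjusted p = 0.409 with an estimated correlation). Microglia and leukocyte markers had a median of 1.75 and 7 of 19 rose (10 adjusted over the list alone), all from low levels, as for Lyz2 (4.99 ± 2.71 to 33.1 ± 14.2 CPM) and the signalling adaptor gene Tyrobp (0.923 ± 0.721 to 7.65 ± 4.20 CPM). The list's share of the counts overlapped between the groups. It was 0.00326, 0.0279 and 0.02% in the naive and 0.0193, 0.0336 and 0.017% in the SOHU libraries. Cd74 and H2-Aa made up 77.2 and 76.8% of that sum in naive replicates 2 and 3. The list's mean level did not overlap, with 2.55, 2.52 and 1.73 log2 CPM in the SOHU libraries and at most 1.65 in the naive libraries. The camera adjusted p was 1.85e-05, and the adjusted p = 0.474 with an estimated correlation. Naive replicate 1 had the lowest mean level of the reactive glia list (3.83 log2 CPM, against 5.70 and 4.76 in the other naive libraries) and of the leukocyte list (-0.67, against 1.65 and 0.97). Of 15 vascular markers 3 rose (4 higher and 2 lower adjusted over the list alone): Kdr (2.50-fold) and Flt1 (2.14-fold), receptors of VEGF, and Pdgfrb (2.42-fold). Of 12 lens genes, 4 rose, also adjusted over the list alone: Cryab, Crybb1, Crybb3 and Bfsp2. In the oligodendrocyte list Cnp alone of 5 passed, with a rise of 2.44-fold (1 higher and 1 lower adjusted over the list alone). None of 8 pigment epithelium and 5 erythrocyte genes passed, also adjusted over the list alone. The camera adjusted p of the vascular, lens, oligodendrocyte, pigment epithelium and erythrocyte lists was 0.099, 0.189, 0.829, 0.926 and 0.829.

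**Figure D3:**
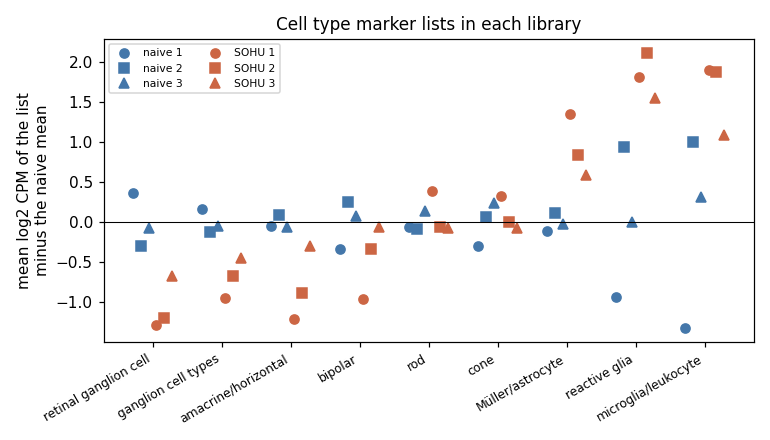
Mean log2 CPM of 9 marker lists (x axis) in each library, minus the mean of the 3 naive libraries (y axis); colours are groups and shapes are replicate numbers. All 3 SOHU libraries lie below the naive libraries for retinal ganglion cell markers and above them for Müller glia and reactive glia, while rod markers overlap.

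Lists of neuronal function fell along with the ganglion cell markers, by a smaller median than the -1.06 of that list. Of 33 genes of axonal transport and the cytoskeleton, 24 fell (27 adjusted over the list alone) with a median of -0.72, including the dynein subunit gene Dync1i1 (log2 fold change -1.11) and the neurofilament genes; of the 28 that are not ganglion cell markers, 19 fell, with a median of -0.66. Of 28 sodium, potassium and HCN channel genes, 15 fell (27 adjusted over the list alone), among them Scn4b, Scn1a (2.24-fold lower) and Kcnip4 (2.24-fold lower), with a median of -0.86. Of 23 glutamate, GABA and glycine receptor genes, 8 fell (10 adjusted over the list alone), for example Gabrb2 (2.03-fold lower) and Grin1 (1.93-fold lower). The camera adjusted p-values were 8.41e-14, 1.82e-13 and 6.34e-07, each with an adjusted p = 0.391 with an estimated correlation. With the scaling to ganglion cell markers, the medians of the 3 lists were 0.29, 0.15 and 0.34, beside 1.06 for all genes.

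Metabolic lists moved in both directions. Of 21 genes of cholesterol synthesis, 12 fell (20 adjusted over the list alone) with a median of -0.77, including Fdft1, which encodes squalene synthase (324 ± 32.6 to 137.7 ± 46.9 CPM, SD, n = 3 each; -1.23, SE 0.22, adjusted p = 0.0128), Cyp51 (1.99-fold lower) and Insig1 (1.79-fold lower). Glycolysis had 10 of 19 genes lower (14 lower and 1 higher adjusted over the list alone), among them Tpi1 (1.72-fold), the neuronal enolase gene Eno2 (1.95-fold) and the pyruvate kinase gene Pkm (1.87-fold). The camera adjusted p was 1.5e-10 for cholesterol synthesis and 2.8e-06 for glycolysis, each with an adjusted p = 0.391 with an estimated correlation. The medians of the 2 lists were 0.21 and 0.42 when scaled to the ganglion cell markers, beside 1.06 for all genes. Nuclear genes of the respiratory chain had a median of -0.18, and 3 of 82 passed (0 adjusted over the list alone): Ndufa10 and Atp5c1 fell and Cox6b2 rose. That list's camera adjusted p was 0.000976, with adjusted p = 0.682 with an estimated correlation and 0.0562 without naive replicate 1. Its median was 0.89 when scaled to the ganglion cell markers, beside 1.06 for all genes, while camera placed it on the higher side and did not call it (adjusted p = 0.11). Of 12 mitochondrially encoded genes, mt-Cytb (1.86-fold), mt-Co3 (1.97-fold) and mt-Atp6 (2.41-fold) rose (10 adjusted over the list alone), with a list median of 0.98 (camera adjusted p = 4e-04; adjusted p = 0.52 with an estimated correlation). Their mean level was 3.67, 3.97 and 3.8 log2 CPM in the naive libraries and 3.90, 5.09 and 4.91 in the SOHU libraries. In the ribosomal protein list 1 of 84 genes passed (0 adjusted over the list alone), Rps27l, a p53 target, with a rise of 1.83-fold (list median 0.03, camera adjusted p = 0.455).

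**Figure D4:**
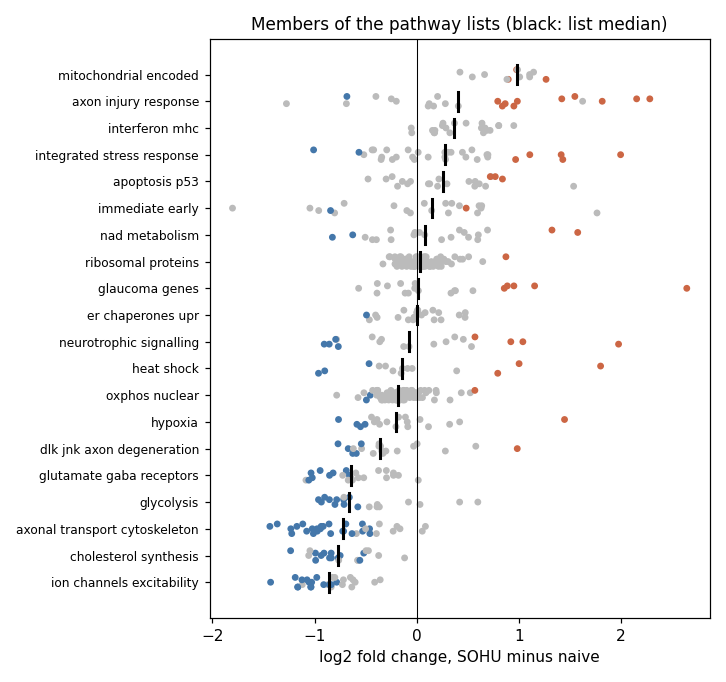
Log2 fold change (x axis, SOHU minus naive) of each tested member of the 20 pathway lists (y axis). Points are genes, red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise, and black bars are list medians, from -0.86 for ion channels to 0.98 for mitochondrially encoded genes.

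Injury and stress genes split between rises and falls. Which cells these changes came from was not tested. Of 23 genes of the axon injury response, 10 rose (11 adjusted over the list alone), among them Lgals3 (16.6 ± 1.14 to 58.7 ± 8.55 CPM, SD, n = 3 each; 1.82, SE 0.16, adjusted p = 0.00762), Crip1 (2.93-fold), Tnfrsf12a (2.68-fold) and Socs3. A fall was seen in 1, the growth cone gene Gap43 (-0.68; 3 lower adjusted over the list alone). Socs3 and 1 further member, Stat3, are also in the reactive glia list, and 8 of the 21 others rose. In the list of DLK and JNK signalling and axon degeneration, 5 of 20 fell (8 adjusted over the list alone), namely Sarm1, which encodes an NAD-consuming enzyme of axon degeneration, Mapk8ip2, Mapk8ip3, Mapk10 and Map2k7. Map4k4 rose 1.98-fold (1 higher adjusted over the list alone). The camera adjusted p was 0.00392 and 0.00299, in each case with an adjusted p = 0.391 with an estimated correlation. Scaled to the ganglion cell markers, the DLK and JNK list had a median of 0.68, beside 1.06 for all genes. Camera did not call it there (adjusted p = 0.413), which is no check on cell shares. In NAD metabolism, Naprt (2.50-fold) and Cd38 (2.98-fold) rose and Nmnat2 and Sarm1 (1.54-fold) fell among 21 genes (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.645). Of 22 genes of apoptosis and the p53 response, Mcl1, Sesn1 and Phlda3 rose by 1.65- to 1.79-fold (5 adjusted over the list alone); the camera adjusted p was 0.0391, with adjusted p = 0.391 with an estimated correlation and 0.103 and 0.0568 without naive replicate 3 and SOHU replicate 2.

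Among 32 ATF4 and CHOP target genes, Nupr1 (3.99-fold), Cebpb (2.70-fold), Cth, Slc3a2 and Psat1 rose and Asns (2.01-fold) and Gars (1.48-fold) fell (9 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.455). Of 22 endoplasmic reticulum chaperone genes only Calr passed, with a fall of 1.41-fold (0 adjusted over the list alone; camera adjusted p = 0.846). In the heat shock list of 14, Cryab (3.48-fold), Bag3 (log2 fold change 1.00) and Hspb1 rose and Hspa8 (1.95-fold), Hspb8 (1.87-fold) and Hsp90aa1 fell (3 higher and 4 lower adjusted over the list alone); its median was -0.15 and its mean 0.02 (camera on the lower side, adjusted p = 0.455). Among 21 immediate early genes Btg2 rose and Dusp1 fell (2 higher and 3 lower adjusted over the list alone); the median was 0.15, the mean -0.01 and the camera adjusted p 0.903. Of 19 HIF target genes, Pdk1, Pfkfb3, Bnip3 and Egln3 fell and the haem oxygenase gene Hmox1 rose 2.73-fold (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0391; adjusted p = 0.391 with an estimated correlation). That call was lost without any library but SOHU replicate 2, with adjusted p-values of 0.0534 to 0.226. Scaled to the ganglion cell markers, it was also lost by camera (adjusted p = 0.939). The list's median there was 0.81, beside 1.06 for all genes, and such a loss is no check on cell shares.

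In the neurotrophic list the receptor genes Fgfr1 (2.06-fold), Il6st (1.89-fold), Osmr (3.94-fold) and Insr (1.49-fold) rose, and genes such as Gfra1, Ret and the growth factor gene Igf1 fell, among 19 genes (4 higher and 4 lower adjusted over the list alone); the median was -0.08, the mean 0.05 and camera on the higher side, with adjusted p = 0.935. Of 19 mouse counterparts of glaucoma-associated genes, Abca1, Cyp1b1 (2.23-fold), Cav1, Cav2 (1.93-fold) and Fndc3b (1.85-fold) rose (5 higher and 1 lower adjusted over the list alone; median 0.02, camera adjusted p = 0.341, fry adjusted p = 0.0365 on the higher side). No gene of the 21 in the interferon and MHC class I list passed, also adjusted over the list alone. The list's median was 0.37 (camera adjusted p = 0.0145; adjusted p = 0.683 with an estimated correlation), and its adjusted p was 0.971 without naive replicate 1, 0.161 without SOHU replicate 2 and 0.123 without SOHU replicate 3.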

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

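The scaling to ganglion cell markers and the omission of pairs of libraries were chosen after the data were seen; the other settings were planned. With all 6 libraries and any planned setting, no gene called here changed sign, and counts of changed genes stayed between 2070 and 3623 beside the 2467 reported. The lower genes rose to 1675 with no low-count filter, where 31942 genes were tested, and to 1729 with DESeq2. The cause was not tested in either case. Of the 128 called genes named in the text other than Nmnat2, 88 kept their side of the threshold in each planned setting with all 6 libraries. Nmnat2 stayed between -0.86 and -0.79 in these settings, with adjusted p-values of 0.000242 to 0.0399. The replicate block gave 2070 changed genes (1178 higher, 892 lower), 1864 of them among the 2467, and Nmnat2 at -0.83 (adjusted p = 0.0399). The deviations of same-numbered libraries from their group means correlated at 0.163, 0.251 and 0.004. Replicates 1 and 2 of each group correlated best with their own number, and replicate 3 of neither group did. Genes with a read numbered 24167, 25898 and 25495 in naive and 23962, 25730 and 25442 in SOHU replicates 1 to 3, in the same order. Xist, Eif2s3y and the interferon list, given below, also kept their order of replicate numbers between the groups. Total counts, Ddx3y and the leukocyte list did not. These values do not decide whether the replicate numbers mark a shared factor, which stays open. The block changed no list call, but the camera adjusted p of the interferon list went from 0.0145 to 4.69e-06.

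Leaving out 1 library, with fewer samples in the fit, gave 0 to 3896 changed genes, 0 to 2051 higher and 0 to 1845 lower. In edgeR the changed, higher and lower genes were 0, 0 and 0 without naive replicate 1 or naive replicate 3 (3919 and 4251 at an unadjusted p under 0.05; 1765 and 2182 by DESeq2; 0 and 0 by limma-voom), 887, 623 and 264 without naive replicate 2, 2017, 1125 and 892 without SOHU replicate 1, 336, 290 and 46 without SOHU replicate 2, and 3896, 2051 and 1845 without SOHU replicate 3. The lowest adjusted p was 0.0676 and 0.063 where no gene passed. No called gene changed sign. Nmnat2 ranged from -0.99 to -0.68 over the omissions, and from -0.91 to -0.68 (adjusted p 0.0564 to 0.116) where it missed the threshold. Without naive replicate 1 and SOHU replicate 1 together, the ends of the first component, 265 genes changed, 233 higher and 32 lower, and Nmnat2 was at -0.57 (adjusted p = 0.117); without naive replicate 2 and SOHU replicate 3, the libraries of different groups that lie nearest each other on that component, 2509 changed. Atoh7, which is not called, moved to -0.41 there, and ranged from -0.25 without SOHU replicate 3 to 0.80 without naive replicate 1. Depth was similar in all libraries. In simulation this design called 8% of 1.5-fold changes, so a gene that missed the threshold is not shown to be unchanged. That simulation changed 200 genes, fewer than the 2467 called in the data, so its call rates may differ from those of the real fit.

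Scaled to the ganglion cell markers, 12063 genes changed, 12061 higher and 2 lower (Gm26783 and Baalc, named after their values were seen), because the median of all genes went from 0.014 to 1.06. The named genes that turned positive in that scaling were Nmnat2 0.22 (adjusted p = 0.546), Aldoa 0.25, Ckb 0.82, Sarm1 0.39, Mapk8ip2 0.25, Mapk8ip3 0.46, Asns 0.037, Gars 0.49, Calr 0.54, Dusp1 0.19, Hspa8 0.089, Hspb8 0.18, Tpi1 0.28, Eno2 0.094, Pkm 0.17, Pdk1 0.55, Pfkfb3 0.47, Bnip3 0.47, Ndufa10 0.56, Atp5c1 0.61, Cyp51 0.005, Insig1 0.20, Gabrb2 0.039, Grin1 0.054, Cartpt 0.042, Calb1 0.35, C1ql2 0.14, Tfap2b 0.25, Map2k7 0.49, Mapk10 0.36, Gap43 0.41, Pou4f2 0.29, Egln3 0.26, Hsp90aa1 0.58, Igf1 0.14, Gfra1 0.23, Ret 0.25, Meis2 0.31, Rgs4 0.18, Syt2 0.13, Syt13 0.003, Atp6v1a 0.47 and Atp6v1h 0.43.

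Of the 34 lists, 19 were called by camera, 7 higher and 12 lower. With an estimated correlation 0 were called by camera. Of these 19, the adjusted p was then 0.391 for DLK and JNK, axon injury, apoptosis, glycolysis, hypoxia, cholesterol, axonal transport, ion channels and receptors. It was 0.409 for both ganglion cell lists, amacrine, Müller and reactive glia, 0.474 for leukocytes, 0.52 for mitochondrially encoded, 0.656 for bipolar, 0.682 for respiratory chain and 0.683 for interferon genes. By fry 8 were called, 7 of them among the 19 and, besides, the glaucoma-associated list (higher, adjusted p = 0.0365). The others had adjusted p 0.0517 for apoptosis, 0.236 for respiratory chain, 0.17 for mitochondrially encoded, 0.0769 for receptors and 0.521 for interferon genes. It was 0.0504 for both ganglion cell lists, Müller and reactive glia, 0.385 for bipolar, 0.0713 for amacrine and 0.187 for leukocytes. Leaving out 1 library left 16 to 19 lists called, and the losses spanned 0.0534 to 0.226 for hypoxia, 0.081 to 0.143 for bipolar, 0.0568 to 0.103 for apoptosis and 0.123 to 0.971 for interferon, with 0.0562 for the respiratory chain without naive replicate 1. Over all omissions the adjusted p was 0.0164 to 0.226, 0.000311 to 0.143, 0.0207 to 0.103, 1.32e-07 to 0.971 and 3.28e-07 to 0.0562 in that order. Scaled to the ganglion cell markers, DLK and JNK (0.413) and hypoxia (0.939) were lost and the respiratory chain turned higher by camera (0.11). The medians of these lists, in that order, were 0.68, 0.81 and 0.89, under the 1.06 of all genes. The cause was not tested.

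The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2467 genes and the highest of the others 0 (1 split gave as many as the real one, itself counted). Each other split mixes naive and SOHU libraries, so a difference between the groups adds to the spread within its sides. The distance from 2467 to 0 is therefore no measure of chance. By camera at the preset correlation the real split called 19 lists and the highest of the others also 19 (2 splits gave as many, the real one counted).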

Other observations

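Gene families were also searched by symbol stem (the letters before the first digit, at least 10 tested genes). After adjustment 7 of 388 tests passed (Fisher's exact test, genes not being independent). Members of the fixed lists were not left out: S100a6, Cd44, Cd38, Cyp1b1 and Atp5c1 are among the genes counted in these stems. The stem S, which takes in genes outside the S100 family as well, held 9 higher genes of 14 (adjusted p = 7.16e-05). Of the S100 genes, which encode small calcium-binding proteins, S100a11 rose 3.29-fold and S100a16 2.92-fold. Stems Cd (13 of 45 higher, adjusted p = 0.00471) and Cyp (10 of 28 higher, adjusted p = 0.00471) rose as well, the latter including Cyp26a1 (4.06-fold; 11.9 ± 3.35 to 48.1 ± 19.6 CPM, SD, n = 3 each) and Cyp26c1 (6.19-fold), which encode enzymes that degrade retinoic acid. Of 10 Frizzled receptor genes of the Wnt pathway 5 rose (adjusted p = 0.0326), for example Fzd5 (2.09-fold) and Fzd8 (1.80-fold).

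On the lower side were 7 of 19 genes of the stem Rgs (adjusted p = 0.00658), with Rgs4 1.92-fold and Rgs8 1.97-fold lower. That stem takes in more than the regulators of G protein signalling. Also lower were 6 of 16 synaptotagmin genes (adjusted p = 0.0159), with Syt2 1.85-fold and Syt13 2.01-fold lower. The stem Atp had 13 of 73 lower (adjusted p = 0.0209), including the vacuolar proton pump genes Atp6v1a (1.48-fold) and Atp6v1h (1.57-fold). The called genes of the Rgs, Syt and Atp stems had median log2 fold changes of -0.94, -0.83 and -0.72. Scaled to the ganglion cell markers, these medians were 0.16, 0.19 and 0.35, beside 1.06 for all genes. Xist and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were counted in all 6 libraries. Xist was at 6.31, 14.7 and 5.70 CPM in naive and 20.1, 43.5 and 11.7 CPM in SOHU replicates 1 to 3, and Eif2s3y was at 8.51, 19.2 and 29.8 CPM and 12.8, 25.7 and 30 CPM.

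The tests below on cell shares and on interferon genes were chosen after the results were seen, and those on gene length before. Ganglion cell markers fell while Müller glia markers rose. A lower share of tagged-cell RNA, with more RNA of every other retinal cell, would raise rod and Müller markers alike. The Müller minus rod level was 0.22 ± 0.18 in naive and 1.06 ± 0.15 in SOHU (log2, SD, n = 3 each), a change of 0.84 with all SOHU libraries above all naive libraries. Amacrine markers moved the other way from Müller markers. These values argue only against an equal rise of all other cells. A lower share of ganglion cell RNA together with more glial RNA is not excluded by them. Gene length bias was argued against, since the ganglion cell median was -1.12 after removal of the length trend. A change of the ganglion cells and a glial reaction after the injection of oil stay open, as does more glial RNA in the pull-down, and none of these was tested.

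Nmnat2 fell by less than most ganglion cell markers, so a lower share of ganglion cell RNA in the pull-down is a candidate explanation. It stays open. Scaled to these markers Nmnat2 had a log2 fold change of 0.22 (95% interval -0.42 to 0.86), which restates the difference from the markers and so supports nothing. Relative to the mean of the markers it was -1.27, -1.05 and -1.24 in naive and -0.94, -0.94 and -1.01 in SOHU. A fall of Nmnat2 and of the markers together within the cells would give the same values, so a biological decrease stays open and was not tested. Gene length does not account for the fall, which was -0.84 after removal of the length trend (adjusted p = 0.0195).

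Interferon and MHC class I genes differed between libraries within each group. The list's mean level was 4.87, 7.62 and 6.66 log2 CPM in naive replicates 1 to 3 and 6.41, 7.61 and 7.35 in SOHU replicates 1 to 3, with the same order of replicate numbers. All 21 genes of the list were higher in naive replicates 2 and 3 than in naive replicate 1, with a median of 8.1- and 3.7-fold. SOHU replicate 2 exceeded SOHU replicate 1 by a median of 2.3-fold, and B2m was at 150.7, 1360 and 1005 CPM in the naive and 624.6, 1803 and 1491 CPM in the SOHU libraries. RNA from leukocytes is a candidate source that stays open. The 17 leukocyte markers other than Cd74 and H2-Aa, which interferon also induces, rose by a median of 6.1- and 3.0-fold from naive replicate 1 to naive replicates 2 and 3. Their median rise was 0.75 and 0.81 of that of the interferon list. With all markers summed, an earlier form of this test, the ratio was 1.05 and 1.67, but Cd74 and H2-Aa made up 77.2 and 76.8% of the sum in naive replicates 2 and 3. Neither form decides, since the markers without these had a median of only 0.27 CPM in naive replicate 1. No biological explanation was tested, since the labels give no difference between these libraries, and a difference in how the samples were handled stays open as well.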
